A study of Homo sapiens with 6 samples.

How the data were processed

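RNA was measured in 6 libraries of IGR37, a human melanoma cell line that carries a doxycycline-switched CTNNB1 transgene (beta-catenin with an added nuclear localisation signal), put in with a piggyBac transposon vector. Per the labels' protocols, 3 libraries came from cells without doxycycline and 3 from cells given 20 ng/ml doxycycline for 24 h, and libraries were made from 500 ng RNA with a kit that reads the 3' end of polyadenylated RNA. Such libraries count a transcript by its last exon, so a transgene that lacks the normal 3' untranslated region of CTNNB1 need not be counted under that name. Nothing in the labels says whether the 3 samples of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical.

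The file analysed here is the authors' own comparison table, with 1 row per gene and no values per library. Per the submitters' processing notes the reads were processed with STAR and edgeR on build hg38; versions, the counting tool, the annotation and the filter on low counts are not given in the sources used here. Per the file headers, the deposited columns are a log2 fold change, the same value as a linear fold change (a ratio), the average log2 CPM (read counts scaled to library size), an F score, a p-value and an adjusted p-value (FDR). The deposited log2 fold change equalled the log2 of the fold change in every row to within 4.26e-14, and the deposited FDR equalled Benjamini-Hochberg values recomputed over all 12617 rows to within a relative 9.01e-13. The header names neither the groups nor the direction of the comparison. The signs are kept here as deposited; "higher" and "lower" mean the positive and negative side of that table. CTNNB1, the induced gene, is positive, which is the sign a doxycycline minus no-doxycycline order would give, but the order is not stated. The F score and the p-value of a row together fix the denominator degrees of freedom of its test: these came to 14.03 in 12052 rows and to 12.03 in 206 rows, took other values in 3 rows, and were not solved in 356 rows, which have a p-value above 0.9 or gave no solution. A loss of 2 is what the quasi-likelihood F test applies to a gene when a group of 3 libraries holds no counts, so those 206 genes are taken to have no reads in 1 group and are given no fold. Their deposited values still enter the counts, medians and list tests unless stated otherwise.

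The table held 12558 rows of genes and 59 rows of ERCC spike-in RNAs, which are synthetic transcripts added to the samples; spike-ins made up 4.43% of the summed average CPM and were left out of gene counts and list tests. In 19 gene rows the symbol had been turned into a calendar date; these rows were kept in counts and never named. Depth per library is not known from this table, so no interval or detection limit that needs it is given. Gene positions are from GENCODE 44 on hg38, matched by symbol for 11559 of the 12558 gene rows.

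The design fixed before the data were examined foresaw counts and a new fit; since the table holds fold changes and p-values only, the fallback written in that design was used. A gene counts as changed when the authors' FDR is under 0.05. The 29 gene lists, also fixed before the data were examined, were tested with cameraPR of limma 3.58.1 in R 4.3.3 on signed z-scores of the deposited p-values, with a preset inter-gene correlation of 0.01, two-sided, and Benjamini-Hochberg adjustment over the 28 lists with measured members. An inter-gene correlation could not be estimated without values per library; a larger preset of 0.05 was tried instead. For each list, its median was also placed among 10000 random lists of the same size matched on average expression. Named genes followed a fixed rule: CTNNB1, ABCB5 and MITF; the 12 largest positive and 12 largest negative log2 fold changes among genes with FDR under 0.05, an average log2 CPM of at least 1 and a symbol that is not a bare identifier; and the members of each list with the smallest p-values (4 per list, 8 for the Wnt feedback, pigmentation and ABC transporter lists). Other list members or genes were chosen after their values were seen and are said to be so where they are not on a fixed list.

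To look for shifts along chromosomes, the log2 fold changes of 8043 genes within 2-fold were corrected for average level and transcript GC by a linear fit, ordered by position on chromosomes 1 to 22 and X, and summarised as medians of windows of 50 neighbouring genes, with 1000 permutations of gene positions. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for this and for the counts. Both methods were tested on simulated data. In 100 simulated tables of 12558 genes without a shift, 2.86% of 2800 list tests had an unadjusted p under 0.05, and a pigmentation list shifted by 1.5 SD was called in 100% of tables. The simulated genes were independent of each other, so this does not test how the list p-values behave when genes of a list are correlated. In simulated window data of 8043 genes, the correlation of a window with the window 2 places on was 0.12 with no step, 0.51 with steps of 0.2 and 0.87 with steps of 0.4 on the log2 scale. Alternatives were a minimum level, an FDR of 0.01, centring on the spike-ins and 4 denominator degrees of freedom. Others left out the genes with no reads in 1 group, the spike-ins, or chromosomes 5, 10, 13 and 15. Centring on the spike-ins used a standard error implied by the F score and is approximate.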

Results

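The study measured the transcriptome of IGR37 melanoma cells before and after nuclear beta-catenin was switched on. Beta-catenin, encoded by CTNNB1, links cadherins to the cytoskeleton at the cell surface and acts in the nucleus as a partner of TCF/LEF transcription factors. The series contrasts 3 libraries without doxycycline with 3 libraries after 24 h of doxycycline at 20 ng/ml, and its title names ABCB5, MITF and melanoma differentiation as the subject. All values below come from the authors' deposited table for this series, which names no groups and is read here as this comparison; it gives a fold change and an edgeR F test per gene and no value per library. Replicate values, their SD and the depth of each library can therefore not be shown, and replicate error enters only through the F test. That test had 14.03 denominator degrees of freedom in most rows, against the 4 that 6 libraries in 2 groups leave. The rest is spread shared across genes, so the FDRs rest on more than each gene's own replicates. The count of changed genes with 4 is given under the dependence on processing. Higher and lower mean the positive and negative side of that table, whose header does not name the order of the groups.

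As labelled, the comparison asked which transcripts differ once nuclear beta-catenin is induced. Whether the differences below come from that induction is not established here. Other readings, among them cells of different karyotype or a table of another comparison, are weighed under Other observations. Of 12558 genes in the authors' deposited table, 6398 (50.9%) had an edgeR FDR under 0.05, 3080 of them higher and 3318 lower. At least a 2-fold change was reached by 3632 of these genes, 1669 higher and 1963 lower. Changes of at least 16-fold were recorded for 368 higher and 456 lower genes. Genes with no reads in 1 group (75 higher, 131 lower) fall in this range, with deposited log2 values of at least 5.26 in size that are not measured folds. Without those genes, 3426 genes were changed at least 2-fold, 1594 higher and 1832 lower. Pigment cell genes were among the higher genes, and many mesenchymal, interferon and keratin genes among the lower. The median log2 fold change of all genes was -0.01, with quartiles at -0.61 and 0.55. The 59 spike-in RNAs had a median log2 fold change of 0.57 in the authors' deposited table; centred on that value, 7992 genes passed 0.05, of which 1424 were higher and 6568 lower, so the share of higher genes moved from 48.1% to 17.8%.

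**Figure D1:**
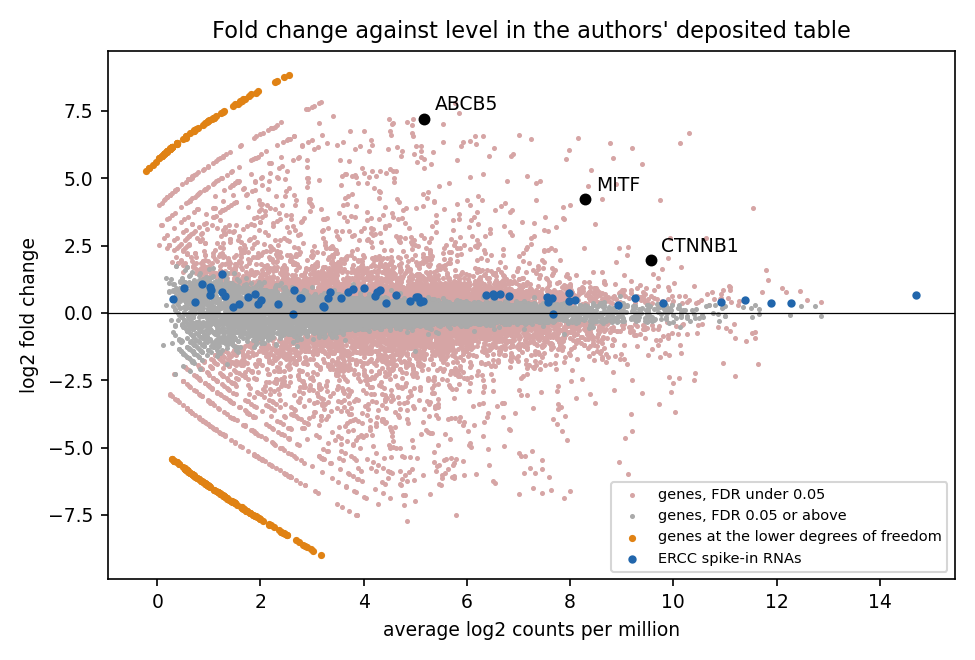
Log2 fold change (vertical axis) against average log2 CPM (horizontal axis) for every row of the authors' deposited table, with called genes, uncalled genes, genes with no reads in 1 group and ERCC spike-in RNAs in separate colours. ABCB5, MITF and CTNNB1 lie at 7.22, 4.22 and 1.96, and the spike-ins centre on 0.57.

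The genes at the ends of the ranking had no reads in 1 of the 2 groups, as judged by their degrees of freedom, so their level in CPM (read counts scaled to library size) is given and no fold. On the higher side these were SLC38A8 with an average of 5.84 CPM, the long non-coding RNAs LINC00589 (5.51) and LINC01317 (3.86), PRDM7 (5.02), the neural POU-domain factor POU3F3 (4.85), SPARCL1 (3.75), SLC5A4 (3.53), FXYD3 (3.23), DPP6 (3.17), DENND2D (3.12) and FCGR2B (3.04), in the authors' deposited table. The lower side was led by the scavenger receptor COLEC12 with 8.96 CPM, the mesenchymal cadherin CDH11 (8.14), OASL (7.85), JPH2 (7.43), the tendon factor MKX (7.27), SLC15A3 (7.07), IFITM1 (6.68), PTGFR (6.43), NPAS3 (5.73), the VEGF receptor FLT1 (5.68), SOX1 (5.57) and CIITA (5.49), the master regulator of class II antigen presentation, again in the authors' deposited table. Each of these genes had an edgeR FDR of 3.75e-05 or smaller. In all, 206 genes had no reads in 1 group, 75 of them higher and 131 lower.

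CTNNB1 was 3.89-fold higher in the authors' deposited table (log2 1.96, edgeR FDR 1.24e-08, average 757 CPM). The gene spans positions 41194741 to 41260096 on the plus strand of chromosome 3 (hg38). MITF, the master regulator of the melanocyte lineage, was 18.6-fold higher in the same deposited table of the authors (log2 4.22, edgeR FDR 5.41e-11, 314 CPM); it lies on the plus strand of chromosome 3 at 69739456 to 69968336. ABCB5, an ATP-driven transporter linked to drug efflux in melanoma, was 149-fold higher in the authors' deposited table (log2 7.22, edgeR FDR 8.89e-10, 36.1 CPM) and lies on the plus strand of chromosome 7 at 20615667 to 20777038. Centred on the spike-ins, the 3 log2 values were 1.39, 3.65 and 6.65. Genes within 2-fold had medians of 0.18 on chromosome 3 and 0.09 on chromosome 7.

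Every measured pigmentation gene was higher: 21 of 21 passed 0.05, and the same 21 did so adjusted over the list alone, with a median log2 fold change of 5.09. SLC24A5, a melanosomal cation exchanger, was 129-fold higher and DCT, a melanin-synthesis enzyme, 102-fold higher in the authors' deposited table. TYR, the rate-limiting enzyme of melanin synthesis, was 88.4-fold, SLC45A2 79.4-fold, the melanoma antigen MLANA 67.1-fold, CAPN3 54.2-fold, TSPAN10 34.1-fold and QPCT 26.3-fold higher in the authors' deposited table. The smallest changes of the list were 0.47 for MLPH and 1.00 for GPNMB on the log2 scale, in the authors' deposited table; the MLPH value lies below the spike-in median. By cameraPR the list stood apart from other genes with an adjusted p of 4.32e-18.

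MITF targets outside pigmentation and lineage regulators moved with them. Of 29 measured MITF targets, 21 were higher and 4 lower (21 and 4 adjusted over the list alone; median 2.40, cameraPR adjusted p = 2.39e-08). Among them the apoptosis inhibitor BIRC7 was 90.2-fold, BCL2A1 81.5-fold, the protease CTSK 51.9-fold and the ceramidase ASAH1 14.0-fold higher in the authors' deposited table. The lower members were HIF1A, CDKN1A, SIRT1 and DIAPH1. Of 19 lineage regulators, 13 were higher and 4 lower (13 and 4 adjusted over the list alone; median 2.37, adjusted p = 0.000849). SOX10, a neural crest factor upstream of MITF, was 78.0-fold higher, ERBB3 136-fold and the endothelin receptor EDNRB 83.0-fold in the authors' deposited table, whereas ZEB1, SOX9, TBX3 and TFE3 were lower.

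The dedifferentiated melanoma list was the mirror image. Of 26 measured members, 24 were lower and 0 higher (25 lower adjusted over the list alone), with a median log2 fold change of -4.02 and a cameraPR adjusted p of 1.24e-13. AXL, a receptor tyrosine kinase of drug-tolerant cells, was 91.0-fold lower, IGFBP3 63.9-fold, NNMT 62.0-fold and the integrin ITGA3 41.5-fold lower in the authors' deposited table. TGF-beta targets showed 15 lower and 2 higher genes of 18 (15 and 2 adjusted over the list alone; median -1.94, adjusted p = 2.25e-05). TGFBI was 51.5-fold and ID1 14.2-fold lower in the authors' deposited table, while BAMBI and ID2 were higher.

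Fibroblast and epithelial markers were mostly lower. Of 9 measured fibroblast markers, 7 were lower and 1, LUM, was higher (median -5.80, adjusted p = 0.000297), with POSTN 78.6-fold, COL3A1 107-fold, COL1A2 61.7-fold and COL1A1 60.2-fold lower in the authors' deposited table. All 7 measured epithelial markers were lower (median -6.35, adjusted p = 0.000849): KRT18 was 103-fold and DSP 6.45-fold lower in the authors' deposited table, and KRT15, KRT8 and TP63 were lower with no reads in 1 group. Without these 3 genes, whose deposited values are not measured folds, the epithelial median was -3.16. The fibroblast median was -5.55 without its 1 such marker. Only 3 of 12 blood and endothelial markers were in the table, CDH5 at 11.7-fold lower, PECAM1 at 5.86-fold lower and CD68 at 1.94-fold higher in the authors' deposited table (CD68 lost the threshold centred on the spike-ins, and CD68 and PECAM1 with 4 denominator degrees of freedom); the list did not pass (adjusted p = 0.709). Adjusted over the list alone, the counts for these 3 lists were the same: 7 lower and 1 higher, 7 lower, and 2 lower and 1 higher.

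**Figure D2:**
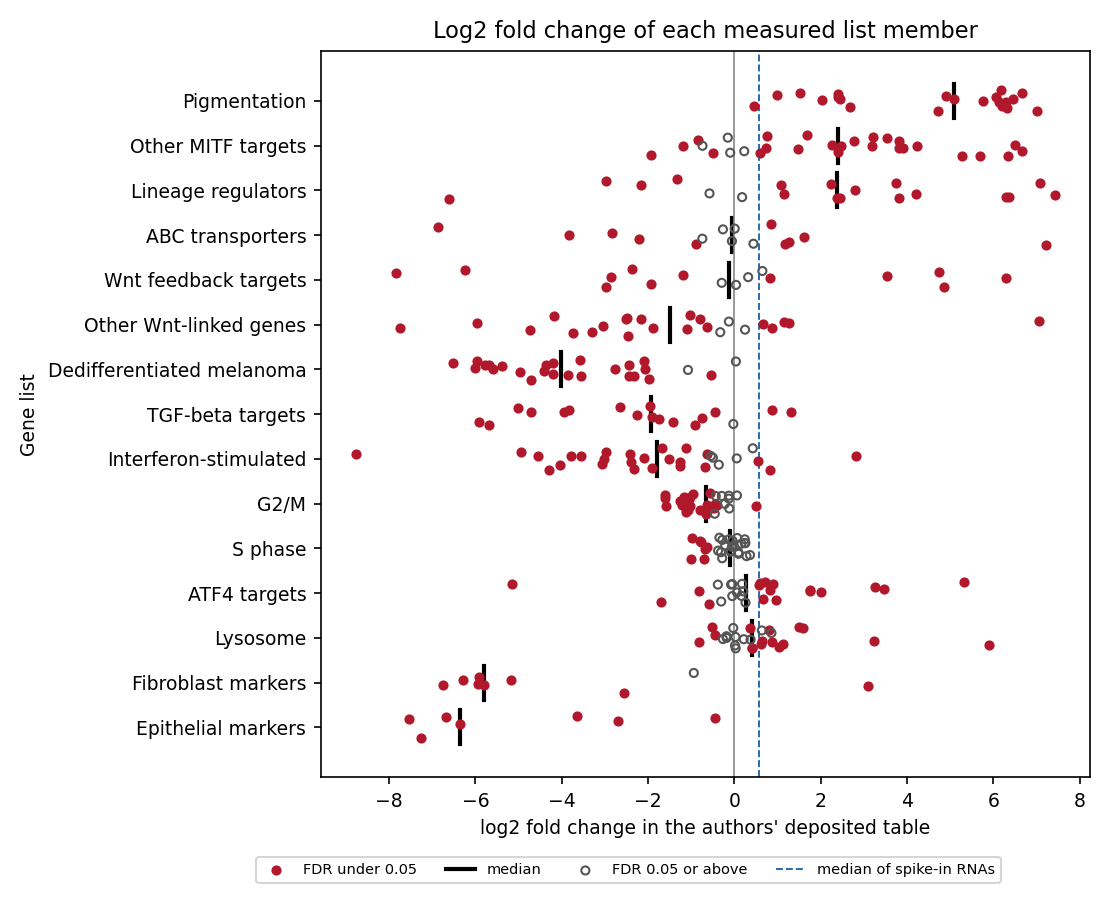
Each point is a measured member of a gene list, placed by its log2 fold change in the authors' deposited table (horizontal axis), with filled points for an FDR under 0.05, a black bar at the list's median and a dashed line at the spike-in median of 0.57. The pigmentation list centres on 5.09 and the dedifferentiated melanoma list on -4.02, while Wnt feedback targets lie on both sides of 0.

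Direct readouts of Wnt signalling split into both directions. Of 16 measured Wnt feedback targets, 5 were higher and 7 lower, also adjusted over the list alone, with a median log2 fold change of -0.13 and a cameraPR adjusted p of 0.652. LEF1, itself a partner of beta-catenin, was 26.9-fold, TNFRSF19 29.1-fold and NKD1 11.6-fold higher in the authors' deposited table. The secreted Wnt inhibitor DKK1 was 76.0-fold, TBX3 7.84-fold, TCF7 7.30-fold and MSX2 3.82-fold lower in the authors' deposited table, and SP5 was lower with no reads in 1 group (average 4.50 CPM). AXIN2, the most widely used feedback target, had a log2 fold change of 0.65 with an edgeR FDR of 0.23 in the authors' deposited table. Of 24 other genes often linked to beta-catenin, 16 were lower and 5 higher (16 and 5 adjusted over the list alone; median -1.50, adjusted p = 0.000297), with TCF4 214-fold, EPHB2 62.8-fold, JUN 13.3-fold and CD44 3.72-fold lower in the authors' deposited table; several of these also have other regulators.

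Among 38 measured Wnt pathway components 6 were higher and 13 lower (7 and 13 adjusted over the list alone; median -0.14, adjusted p = 0.305). The corepressor TLE4 was 68.1-fold, the receptor FZD2 14.6-fold and BCL9L 4.59-fold lower in the authors' deposited table. Cadherins went in both directions: CDH1 was 24.7-fold higher, CDH2 6.68-fold and CDH13 72.4-fold lower in the authors' deposited table. CDH1 averaged 5.87 CPM, against 80.8 for CDH2, so its fold rests on a very low level in 1 group. Of 11 measured junction genes 3 were higher and 6 lower, also adjusted over the list alone (median -1.80, adjusted p = 0.256); that median lay outside the central 95% of random lists matched on level (-0.68 to 0.59). Without CDH11, which had no reads in 1 group, the junction median was -1.04.

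ABC transporters went both ways, with ABCB5 the most changed as deposited and ABCC3 the most changed when centred on the spike-ins. Of 15 measured, 5 were higher and 5 lower, also adjusted over the list alone; the list did not pass (adjusted p = 0.951), and its test pointed up while its median (-0.06) and mean (-0.34) were negative. ABCA5 was 3.08-fold, ABCC5 2.26-fold and ABCB6 1.80-fold higher in the authors' deposited table, the last no longer past 0.05 when centred on the spike-ins. ABCC3 was 116-fold, the cholesterol exporter ABCA1 14.2-fold, ABCG2 7.11-fold and ABCG1 4.60-fold lower in the authors' deposited table.

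Interferon-stimulated and antigen presentation genes were mostly lower. Of 30 measured, 22 were lower and 3 higher, also adjusted over the list alone (median -1.79, adjusted p = 4.70e-06), with BST2 19.7-fold, ISG15 16.3-fold, IFIT3 11.6-fold and HLA-B 7.91-fold lower in the authors' deposited table. HLA genes resemble one another closely, so reads may be split among them. Of 16 NF-kappaB targets, 4 were higher and 5 lower (4 and 7 adjusted over the list alone; median -1.03, adjusted p = 0.364, the median lying outside the central 95% of matched random lists, -0.59 to 0.58); TNFAIP3 was 15.5-fold higher, CCL2 41.5-fold, TNFAIP2 5.53-fold and NFKBIA 2.94-fold lower in the authors' deposited table.

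Mitotic genes were modestly lower. Of 30 G2/M genes, 21 were lower and 1 higher (23 and 1 adjusted over the list alone; median -0.65, adjusted p = 2.25e-05), with KIF20A 3.03-fold, CCNB1 2.41-fold, TPX2 2.30-fold and AURKA 2.26-fold lower in the authors' deposited table; tested on log2 fold changes instead of p-values, the list had an adjusted p of 0.213. Of 28 S-phase genes, 7 were lower and 0 higher, also adjusted over the list alone (median -0.11, adjusted p = 0.256, or 0.021 centred on the spike-ins). E2F1 was 1.96-fold, RRM1 1.73-fold, RRM2 1.71-fold and GINS2 1.60-fold lower in the authors' deposited table. ERK-dependent transcripts had 7 higher and 8 lower genes of 23 (8 and 8 adjusted over the list alone; median -0.18, adjusted p = 0.927), with EGR3 46.9-fold higher and EPHA2 23.5-fold, FOSL1 5.66-fold and PHLDA1 2.31-fold lower in the authors' deposited table. EGR3 averaged 4.47 CPM, so its fold rests on a very low level in 1 group. Of 22 p53 targets, 4 were higher and 8 lower, also adjusted over the list alone (adjusted p = 0.951; median 0.04, mean -0.21 and the test pointing down). GDF15 was 40.1-fold and AEN 2.23-fold higher, PLK2 4.04-fold and DDB2 2.55-fold lower in the authors' deposited table.

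Metabolic and stress lists shifted less. ATF4 targets had 13 higher and 4 lower genes of 27, also adjusted over the list alone (median 0.26, or -0.31 relative to the spike-ins; adjusted p = 0.0333, or 0.153 with a preset correlation of 0.05 and 0.0608 centred on the spike-ins; the median lay inside the central 95% of matched random lists, -0.39 to 0.29). GDF15 (40.1-fold), CTH (9.53-fold) and WARS (3.38-fold) were higher and STC2 was 35.3-fold lower in the authors' deposited table, while ATF4 itself had a log2 fold change of 0.18 with an edgeR FDR of 0.375. Lysosomal genes had 13 higher and 3 lower of 27 (14 and 3 adjusted over the list alone; median 0.42, or -0.15 relative to the spike-ins; adjusted p = 0.0223, or 0.124 with the larger correlation and 0.131 centred on the spike-ins), with ATP6V0D2 59.6-fold, WIPI1 9.35-fold, HEXA 2.83-fold and ATP6V1C1 2.17-fold higher in the authors' deposited table. ATP6V0D2 averaged 2.52 CPM, so its fold rests on a very low level in 1 group. Nuclear genes of oxidative phosphorylation had 12 higher and 1 lower of 22 (13 and 2 adjusted over the list alone; median 0.39, or -0.18 relative to the spike-ins; adjusted p = 0.0184, or 0.0993 with the larger correlation and 0.477 centred on the spike-ins). COX5A was 1.95-fold, COX7A2 1.88-fold, NDUFA4 1.84-fold and COX5B 1.79-fold higher in the authors' deposited table; the last 3 did not pass when centred on the spike-ins.

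Glycolysis and hypoxia genes had 14 lower and 3 higher of 26, also adjusted over the list alone (median -0.43, adjusted p = 0.0204, or 0.118 with the larger correlation). NDRG1 was 10.2-fold, VEGFA 5.58-fold and the glucose carrier SLC2A1 3.53-fold lower and HK2 4.85-fold higher in the authors' deposited table. Of 20 sterol genes 8 were higher and 3 lower, also adjusted over the list alone (adjusted p = 0.152); DHCR7 was 11.1-fold and EBP 2.00-fold lower and FDFT1 1.96-fold higher in the authors' deposited table. Chaperones of the endoplasmic reticulum had 5 higher and 1 lower of 17 (5 and 0 adjusted over the list alone; adjusted p = 0.343), among them HERPUD1 2.10-fold, DNAJC3 1.68-fold, HYOU1 1.57-fold and PDIA6 1.44-fold higher in the authors' deposited table, none of them past 0.05 when centred on the spike-ins. Heat shock genes had 3 higher and 2 lower of 12, also adjusted over the list alone (adjusted p = 0.840; median 0.03, mean -0.12 and the test pointing up): HSPE1 was 1.91-fold, HSPH1 1.87-fold and HSPD1 1.80-fold higher and BAG3 5.33-fold lower in the authors' deposited table; HSPH1 and HSPD1 lost the threshold centred on the spike-ins.

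Signs of library make-up were also measured. Of 23 ribosomal protein and translation transcripts, 7 were higher and 0 lower (6 adjusted over the list alone; median 0.21, or -0.36 relative to the spike-ins; adjusted p = 0.0660, or 0.0382 with ranks), with RPLP1 1.90-fold, RPS3 1.73-fold, RPS18 1.61-fold and RPL5 1.39-fold higher in the authors' deposited table; centred on the spike-ins, RPS3 and RPS18 lost the threshold and RPL5 turned negative without passing it. Of 10 histone and structural RNAs, 3 were higher and 2 lower, also adjusted over the list alone (adjusted p = 0.791; median 0.04, mean -0.17 and the test pointing up). NEAT1 was 2.29-fold, HIST1H1C 1.61-fold and HIST1H4C 1.43-fold higher and HIST1H2BD 4.45-fold lower in the authors' deposited table; centred on the spike-ins, HIST1H1C lost the threshold and HIST1H4C turned negative without passing it. None of the 13 mitochondrially encoded mRNAs was listed in the table.

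Fold changes also differed between chromosomes. Among genes within 2-fold, the median log2 fold change ran from -0.43 over 259 genes of chromosome 10 to 0.43 over 103 genes of chromosome 13. It was -0.28 on chromosome 5 and 0.34 on chromosome 15. Chromosomes 9 (-0.28), 20 (-0.28), 18 (0.30) and 21 (0.33) were shifted as far as chromosome 5 or further. Leaving out chromosomes 5, 10, 13 and 15 therefore does not remove the shifts. Over all placed genes, whatever their change, the medians were -0.67 over 444 genes of chromosome 10 and 0.73 over 212 genes of chromosome 13, with -0.42 on chromosome 5 and 0.55 on chromosome 15. Corrected window medians of 50 neighbouring genes had an SD of 0.209, against at most 0.116 in 1000 permutations of gene positions, and correlated with the window 2 places on at 0.73, against at most 0.32 in the permutations (p = 0.001 for both, the smallest they can give). This correlation is across genome windows, which are not independent replicates. What these shifts may mean for reading the gene results as an induction effect is weighed under Other observations.

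**Figure D3:**
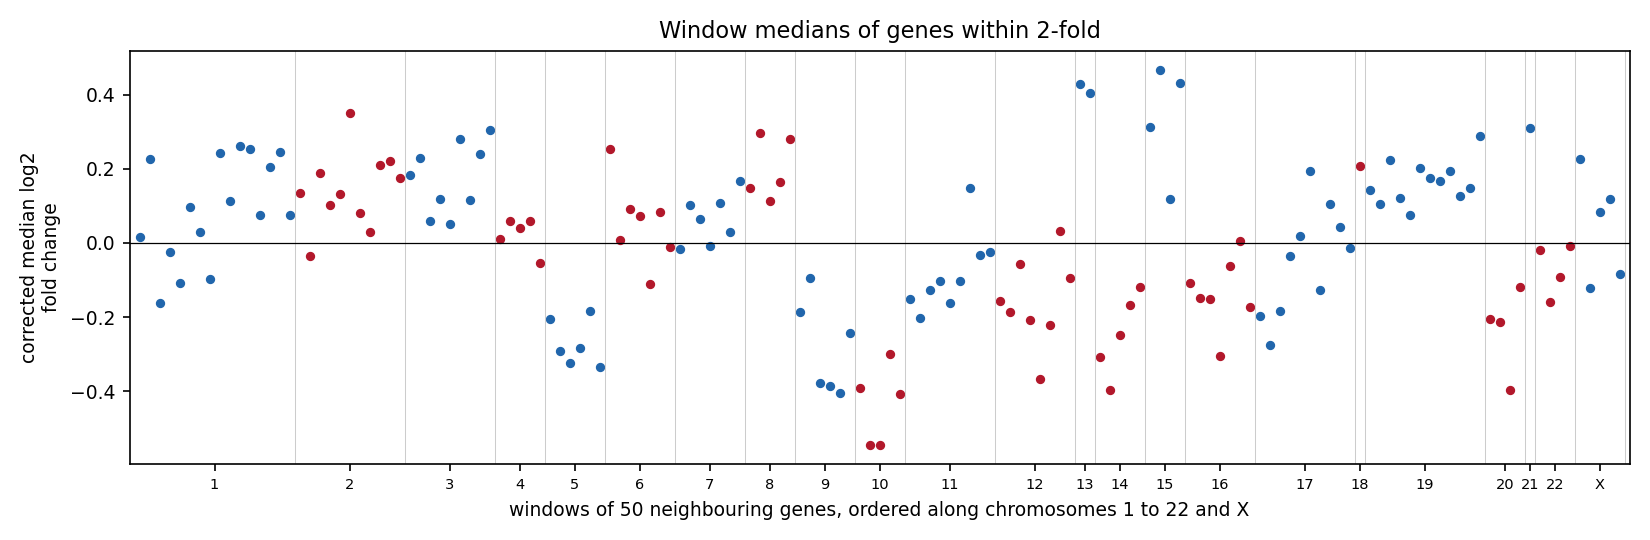
Corrected median log2 fold change (vertical axis) of windows of 50 neighbouring genes within 2-fold, ordered along chromosomes 1 to 22 and X (horizontal axis), 1 point per window and colours alternating by chromosome. Neighbouring windows tend to have similar levels, with exceptions such as windows of chromosomes 1, 11 and 17, and with chromosome 10 below 0 and chromosomes 13 and 15 above it.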

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

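The spike-in RNAs are outside the comparisons of genes, and the tests on them were chosen after their values were seen. Of the 59 ERCC spike-ins, 57 had a positive log2 fold change in the authors' deposited table, with a median of 0.57 (1.48-fold) and quartiles of 0.40 and 0.69; 28 had an FDR under 0.05, all positive. A loss or gain of reads that differs between low and high spike-in levels was tested as a technical explanation, and both conditions stated for it, for and against, were met. The log2 fold change fell with level (slope -0.019 per log2 unit, 95% bootstrap interval -0.039 to -0.0023; Pearson r = -0.26, permutation p = 0.0465; Spearman rho = -0.25, permutation p = 0.0583; 59 spike-ins, which are not independent samples), which speaks for it. The steepest slope in the interval gives 0.563 over the whole range of levels, just under the median shift of 0.570, which was the condition against it. The 30 spike-ins above and the 29 below the median level, a comparison whose limit was chosen after the medians were seen, had medians of 0.56 (95% bootstrap interval 0.44 to 0.62) and 0.60 (0.53 to 0.77), which argues against it as the source of the whole shift, though not against a smaller trend. The amount of spike-in added and the RNA content of the cells were not tested and stay open.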

How the results depend on the processing

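No paired analysis was possible because the table used here holds 1 combined comparison with no values per library; for the same reason the planned changes of normalization, filter and test tool, the pseudocounts, the omission of single replicates, an estimated inter-gene correlation, fry, and other splits of the 6 libraries were not run. Settings other than an FDR of 0.01 and a minimum level for genes, and ranks for lists, were chosen after seeing the data. The count of 6398 changed genes was 6076 with a minimum level, 4781 at an FDR of 0.01 and 7992 centred on the spike-ins, and fell to 4142 (1966 higher, 2176 lower) with 4 denominator degrees of freedom; the genes changed at least 2-fold were between 3031 and 4784. CTNNB1, ABCB5 and MITF stayed higher and past the threshold under each setting that keeps them. Centring on the spike-ins turned 3 named genes, PDIA6 (-0.046), RPL5 (-0.094) and HIST1H4C (-0.050), and 13 others lost the threshold with their sign unchanged, as did 5 with 4 denominator degrees of freedom (DNAJC3, CD68, PECAM1, RPL5 and HIST1H4C). Of 28 lists 14 passed, and 9 with the log2 fold change as the statistic, which lost the G2/M, ATF4, oxidative phosphorylation, glycolysis and lysosome lists. With a preset correlation of 0.05, 10 passed, without the ATF4, oxidative phosphorylation, glycolysis and lysosome lists. Centred on the spike-ins 12 passed, without the ATF4, oxidative phosphorylation and lysosome lists and with the S-phase list; with ranks 15 passed, with the ribosomal protein list. Lists whose test changed direction had not passed before and did not pass after: centred on the spike-ins, Wnt feedback (adjusted p = 0.873), ERK-dependent (0.961), heat shock (0.999) and ribosomal protein (0.999); with a minimum level, p53 (0.949) and blood and endothelial (0.949); on log2 fold changes, ABC transporters (0.772), ERK-dependent (0.912), heat shock (0.937) and histone (0.912); and centred on each chromosome's median, ABC transporters (0.961). The cause of these changes was not tested beyond the construction of each setting. Depth per library is unknown, so a missing gene cannot be told from one below the authors' filter.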

Other observations

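The gene families in this paragraph were chosen after the table was seen, so only counts past 0.05 and medians of log2 fold changes are given, with no test of a family. Of 18 measured Schwann cell and glial genes, picked from genes seen in this table and sharing ERBB3 and SOX2 with the lineage list, 16 were higher and 0 lower (median 5.60). FABP7, a fatty acid binding protein of glial precursors, was 205-fold, POU3F2 111-fold and S100B 97.0-fold higher in the authors' deposited table, and SOX2, SOX8 and PMP2 were higher with no reads in 1 group. Class II antigen presentation genes were lower in 8 of 9 (median -3.62), with no reads of CIITA and CD74 in 1 group and a log2 fold change of -5.43 for HLA-DRA in the authors' deposited table. Of 8 keratins, 7 were lower (median -6.21), among them KRT18, KRT15, KRT8 and KRT10 of the epithelial list. KRT7, KRT8 and KRT15 had no reads in 1 group, so the keratin median rests in part on values that are not measured folds. Of 25 collagens, 16 were lower and 6 higher (median -1.98), COL1A1, COL1A2 and COL3A1 of the fibroblast list among the lower; COL9A3 was 32.6-fold higher in the authors' deposited table. Of 28 HOX genes, which mark body position, 15 were lower and 2 higher (median -0.71). Of 10 S100 genes 3 were higher and 7 lower (median -1.47).

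The pattern that most invites a second look is the size and kind of the change: a melanocytic programme higher, a mesenchymal programme lower, and 206 genes with no reads in 1 group. The test for copy number was set before its result was seen; the tests of TCF/LEF targets, the stress response, fibroblasts and chromosome medians were chosen after their values were seen. Window medians correlated with the window 2 places on at 0.73, over the 0.3 set in advance. Chromosome medians of higher and lower expressed genes agreed in sign on 22 of 23 chromosomes. Across chromosomes they had a Pearson r of 0.94 (permutation p = 1e-05, the smallest it can give) and a Spearman rho of 0.94, for which no p was computed. Both sets of genes come from the same comparison, in which chromosome medians were already seen to differ. Their agreement shows that the shifts hold at both levels of expression and is not separate evidence for copy number. The window correlation and this agreement could both come from a difference in gene copy number. As a hypothesis the 2 groups may hold cells of different karyotype (another clone or line, a selected subpopulation, or a table of another comparison). Chromatin changes over whole chromosomes stay open, and genotypes or values per library would be needed to decide.

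Other explanations of the same pattern were tested against conditions stated for each. An integrated stress response to doxycycline was to be set aside if the upper 95% bootstrap bound of the ATF4 list's median lay below 1 on the log2 scale, and the median was 0.26 with an interval of -0.05 to 0.83. That condition decides nothing, because 13 members were higher and 4 lower. The list passed on the higher side (adjusted p = 0.0333) but not with a preset correlation of 0.05 (0.153), centred on the spike-ins (0.0608) or on log2 fold changes (0.248), and ATF4 itself had a log2 fold change of 0.18 with an FDR of 0.375 in the authors' deposited table; the stress response stays open, without a doxycycline control that lacks the transgene. Fibroblasts mixed into the cells on the lower side were to be set aside if any marker was higher: LUM was, with a log2 fold change of 3.10 in the authors' deposited table, but at an average of 3.16 CPM, against 93.4 for POSTN and 47.4 for COL1A2, and 1 weakly expressed gene does not exclude a small admixture. As the cause of the whole pattern, fibroblasts would have to make up 97.1% of the lower side for the median pigmentation gene, yet the median of the 9 markers averaged 22.9 CPM, so at most about 45.8 in 1 group, against 22.3 for the median gene and 152 for the ninth decile; this argues against it. Activation of TCF/LEF target genes by beta-catenin, the effect the design names, called for a clearly positive median of the feedback list. It also called for a cameraPR test past 0.05 on the higher side, and was to be set aside if that test passed on the lower side. The median was -0.13 and the cameraPR adjusted p was 0.652, so the condition for it failed and the condition against it was not met. The other genes linked to beta-catenin passed on the lower side (cameraPR adjusted p = 0.000297), but several have other regulators. The feedback list had members on both sides, so it cannot decide, and TCF/LEF activation stays open.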
